A study of Glycine max with 12 samples.

How the data were processed

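Soybean (Glycine max) stem RNA was hybridised to 12 two-colour cDNA microarrays. Per the labels, the RNA came from the uppermost inch of stem below the unifoliate node of 15-day-old plants grown at 23 °C. The day length was 12 h for the first 14 days and 16 h later, and the light was 160 to 180 µmol. The stem had been cut, and an agar plug with mycelium of the white mould fungus Sclerotinia sclerotiorum, isolate 105HT, was placed on the cut surface. Tissue was taken 8 h or 14 h after inoculation. The plants were Williams 82, a soybean cultivar, or PI194639, a plant introduction held under that number. They are abbreviated S and R as in the labels' titles, so that S14 is RNA of Williams 82 at 14 h. No uninoculated or mock-inoculated sample was analysed here. Effects of time of day, light or cutting could therefore not be separated from those of infection.

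The 12 arrays form 3 replicate loops of 4 arrays. In each loop S14 was hybridised with S8, S8 with R8, R8 with R14 and R14 with S14, the first-named RNA in Cy3 and the second in Cy5, per the labels. The series' design text speaks of a loop with 3 biological repeats and of 2 technical repeats with dye swaps. Whether each deposited value is from 1 slide or an average over swapped slides is not given in the sources used here. Whether each biological repeat pooled several plants is not given either.

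The authors deposited 1 log ratio of the 2 channels per probe and array, treated here as log2. The base of the logarithm, the numerator of the ratio, the background correction and the normalization are not given in the sources used here. The values were already centred by the authors, with array medians from -0.0083 to 0.0035 and SDs over probes from 0.309 to 0.528. Signal over background was not analysed here, so precision was judged from the 3 loops alone.

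Because the numerator is not stated, no direction was assigned. Signs are given as deposited. For the times, positive means the sign found on the S14-against-S8 arrays, and for the genotypes the sign found on the S8-against-R8 arrays. Genes with the same sign in one comparison lie on the same side, and which RNA was higher stays open. The time arrays and the genotype arrays may also run opposite ways with respect to their titles, so signs of a time comparison and of a genotype comparison were not set against each other. Within each kind the signs went with the titles, though weakly for the genotypes. Arrays naming the times in opposite order correlated negatively across probes in every loop (r = -0.46, -0.35 and -0.65). Those naming the genotypes in opposite order did so at r = -0.42, -0.26 and -0.11. The R14-against-S14 arrays of loops 2 and 3 correlated with each other at only 0.05. That of loop 2 correlated at -0.31 and -0.37 with the S14-against-S8 arrays of loops 1 and 3.

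Of 19200 probes, 555 had no value on any array and 243 had values on some arrays only. Exact zeros were far more common than neighbouring values, at 414 to 1736 per array, against 0 to 8 values at plus or minus 0.0001. They were kept as deposited, except that 130 probes at 0 on all 12 arrays were left out. The tests ran on 18272 probes.

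Probe names came from the platform annotation. It gave 1 gene to 1158 probes, several genes to 13 and none to 18029. Of 527 genes, 523 were matched in the RefSeq gene table of assembly Glycine_max_v4.0, which was used for synonyms only. No gene description was used. A spotted cDNA can hybridise with transcripts of close paralogs, so a symbol such as CHS1 stands for a gene family rather than for 1 copy.

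In each loop the relative levels of the 4 RNAs were solved by least squares from the 4 log ratios. A comparison of 2 neighbouring RNAs then weights its direct array by 0.75 and each of the other 3 by 0.25, and a dye effect common to the 4 arrays cancels. The averages over both genotypes or both times use the direct arrays alone, and their values do not depend on whether the genotype arrays were turned. The 12 RNA levels per probe were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, statmod 1.5.0), with the loop as a block and 1 spread shared by the 4 RNAs. The fit had 6 residual and 3.91 prior degrees of freedom. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes of a comparison. The 7 comparisons, the main fit and most alternatives were fixed before the data were examined. Each value is given with its SD over the 3 loops.

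The loops are paired by design, since every array holds 2 RNAs of 1 replicate number. The alternative without the block treats the 12 arrays as independent. Other alternatives fixed beforehand were a dye term, the direct arrays alone, centring, scaling to equal spread, a looser filter on missing values, robust moderation, a 1.5-fold minimum, an adjusted p of 0.1, averaging of a gene's probes, and leaving out each loop. Added after seeing the data were turned signs of the genotype arrays, omission of probes with an exact 0, a test of each comparison on its own 3 loop values, and set tests on averaged genes.

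The pooled spread did not suit every comparison equally. The variance between loops was 1.51 times the assumed one for the times averaged over genotypes, 1.21 times for time in PI194639 and 1.09 times for the averaged genotypes. It was 0.697 times for time in Williams 82, 0.638 and 0.85 times for the genotypes at 8 h and 14 h, and 0.396 times for the interaction. Adjusted p-values are therefore too small where the factor is above 1 and too large where it is below 1.

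The fit was tested on simulated loops of 18272 probes with 200 changed probes in S14. For time in Williams 82 it recovered 148 with 4 false calls: 12 of 50 at a log ratio of 0.5, 39 of 50 at 1, 47 of 50 at 1.5 and 50 of 50 at 2. For the interaction it recovered 112 of 200. Of 21 simulated lists, the single moved list passed camera and fry and no unmoved list did. The noise was simulated independently for each probe, so this could not show false passes from correlation within a list. In the real lists the estimated correlation was, for example, 0.32 for flavonoid and 0.53 for cell division genes.

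Named genes followed a rule fixed before the data were examined. Per comparison, these were the 10 largest absolute log ratios on each side among called probes with 1 gene name and the same sign in all 3 loops, with the probe of smallest p per gene, plus up to 3 members per gene list with the smallest p. Where none passed, the 5 smallest p were taken. Of 21 gene lists fixed beforehand, 20 held a named probe and the germin list held none. Without descriptions, members were assigned by symbol after the symbols were seen but before their values were tested, and 5 lists were added in the same way. The 21 lists with at least 5 probes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with fry beside them, adjusted over lists.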

Results

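The 12 arrays compared 4 stem RNAs, 2 soybean genotypes at 2 times after inoculation with Sclerotinia sclerotiorum, in 3 replicate loops with 1 array per pair and loop. Each array gave 18582 to 18644 log ratios. The series addresses the early response of soybean stem to the fungus. Its design asks how transcript levels differed between 8 h and 14 h in each genotype, how they differed between the genotypes at each time, and whether the change over time differed between the genotypes. Replicates are called biological repeats in the design text. All values are log ratios as deposited, taken as log2, with the SD over 3 loops. Which RNA a positive value favours is not stated.

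In Williams 82, MMP2, PR-10 and histone H4 lay on one side of the comparison between 14 h and 8 h, and GF14A, NOD33 and MIPS on the other. The largest named value on the positive side was that of MMP2, a matrix metalloproteinase, at 2.31 ± 0.3 (limma adjusted p = 0.015), which is 4.95-fold if the base is 2. A probe of OAS-TL3, of cysteine synthesis, was at 2.02 (adjusted p = 0.035), but the OAS-TL3 probe with the smallest p lay on the other side, at -0.59 (adjusted p = 0.027). The isoflavone reductase LOC547659 was at 1.64 ± 0.34 (adjusted p = 0.028), the wound-induced protein gene WIN at 1.42 ± 0.47 (adjusted p = 0.023) and PR-10, of the ribonuclease-like pathogenesis-related proteins, at 1.31 ± 0.18 (adjusted p = 0.011). Histone H4 was at 1.21 ± 0.19 and sulfite reductase SIR at 1 ± 0.3. Flavanone 3-hydroxylase F3H was at 1 ± 0.33 and the beta-amylase gene BMY2 at 0.91 ± 0.4. LOC547566 at 1.27 ± 0.087 and SC-03 at 1.12 ± 0.4 lay on the same side. SC-03 is also carried by a second probe, which lay on the other side when the genotypes were averaged.

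On the negative side the 14-3-3 gene GF14A, at -2.13 ± 0.2, had the smallest adjusted p of all probes (0.00013). A second GF14A probe was at -0.15. The nodulin gene NOD33 was at -2.12 ± 0.41 (adjusted p = 0.0094). The beta-amyrin synthase AMS1, of triterpene synthesis, was at -1.58 ± 0.59. The glutathione S-transferase GST24 was at -1.4 ± 0.43, and myo-inositol-1-phosphate synthase MIPS at -1.3 ± 0.16, with all 4 MIPS probes called. LOC547648 reached -2.25 ± 0.79, LOC548016 -1.84 ± 0.92, LOC547630 -1.52 ± 0.94, PGLCAT8 -1.46 ± 0.54 and LOC100037476 -1.21 ± 0.74. Asparagine synthetase AS2 was at -1.07 ± 0.094, and the second isoflavone reductase IFR2 at -0.73 ± 0.051. Catalase CAT5 was at -0.93 ± 0.58, lipoxygenase VLXB at -0.87 ± 0.37 and the cellulase CEL12 at -0.84 ± 0.17.

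In all, 646 of 18272 probes passed the threshold for time in Williams 82, 210 positive and 436 negative, each with the same sign in all 3 loops. Of these, 76 carried 1 gene name, for 45 genes. Tested on its own 3 loop values, this comparison called 1651 probes, 624 of them among the 646, and all 32 genes named for it kept their call. That test reuses the 3 loop values and favours probes with the same sign in all 3 loops, as all 646 had. With a gene's probes averaged, 15 of the 32 lost their call. On the direct arrays alone all 32 lost it, as they did without loop 1, and 31 lost it without loop 3. With the signs of the genotype arrays turned, which the labels leave open, 582 probes passed, 380 of them among the 646. The calls of 9 of the 32 genes then ended, among them LOC548016 (adjusted p = 0.058), AMS1 (0.087), LOC547630 (0.051), GST24 (0.1) and LOC100037476 (0.058). Without loop 1 no probe passed (2246 at an unadjusted p under 0.05), without loop 3 only 8 did, and without loop 2 the count was 1262.

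In PI194639 many of the same genes stood at the ends of the time comparison. H4 was at 1.15 ± 0.28 (limma adjusted p = 0.025), PR-10 at 1.09 ± 0.24 (adjusted p = 0.043), the peroxidase PRX4 at 0.84 ± 0.3 (adjusted p = 0.039) and SC-03 at 0.81 ± 0.23 (adjusted p = 0.045). On the negative side were NOD33 at -1.7 ± 0.95, GF14A at -1.47 ± 0.15 (adjusted p = 0.0041), PK3 at -1.13 ± 0.31 and LOC547643 at -1.1 ± 0.32. MIPS was at -0.97 ± 0.29 and AS2 at -0.89 ± 0.37.

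For PI194639, 133 probes passed, 41 positive and 92 negative. All 133 had the same sign in Williams 82, as all 646 had in PI194639. The lists shared 37 positive probes, where independent lists would share 0.471, and 84 negative probes, against 2.2. Across probes the time values of the genotypes correlated at r = 0.86, and at r = 0.63 on the direct arrays alone. Loops simulated with no effect gave r = 0.21, because the estimates share arrays. The covariance was 0.1 against a simulated 0.00707. Direct arrays of different loops share no RNA, and between them r ranged from 0.09 to 0.59. The PI194639 count was 0 on its own 3 loop values (2481 at an unadjusted p under 0.05) and 0 without loop 1 or loop 3. It was 1528 without loop 2 and 644 with the signs of the genotype arrays turned. Over all probes the PI194639 time values of loop 2 correlated with those of loops 1 and 3 at r = 0 and 0.13, against 0.65 between loops 1 and 3.

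**Figure D1:**
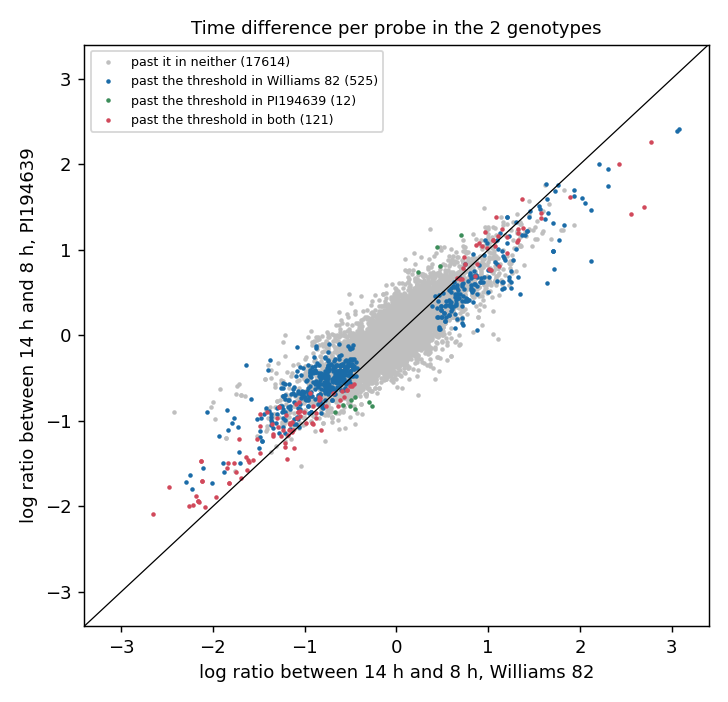
Each point is 1 of 18272 probes, with its log ratio between 14 h and 8 h in Williams 82 on the x axis and in PI194639 on the y axis, both as deposited; the line marks equal values. The 121 probes past the threshold in both genotypes lie in the same quadrants as the 525 past it in Williams 82 alone and the 12 past it in PI194639 alone.

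No probe passed the test of the difference between these time changes (limma interaction, 167 probes at an unadjusted p under 0.05). The array-level fits also called none. Fewer calls in PI194639 are thus not a tested difference between the genotypes. The 5 named genes with the smallest p did not pass, each at an adjusted p of 1. GST24 had an interaction value of -1 ± 0.37, LOC547837 0.88 ± 0.28, GF14A -0.66 ± 0.12, the glycosyltransferase UGT1 -0.54 ± 0.25 and the glutathione S-transferase LOC547581 -0.54 ± 0.2. With the genotype arrays turned, 4 of them changed sign, but if the titles are right the turned value holds no interaction. Of the gene lists, jasmonate and ethylene genes alone passed camera (adjusted p = 0.049), and the adjusted p was 0.86 with an estimated correlation. None of their 53 probes passed. Simulated interactions were recovered for 112 of 200 changed probes, but recovery by size was not computed for the interaction. In the simulation 2.73% of unchanged probes had an unadjusted p under 0.05, against 167 of all 18272 probes here. The variance between loops was 0.396 times the assumed one, so the real test was the stricter. Which differences were within its reach is not known.

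Averaged over both genotypes, the comparison between the times called more genes. Chalcone synthase CHS1, which opens flavonoid synthesis, was at 1.39 ± 1.1 (limma adjusted p = 0.023), and LOC547659 at 1.61 ± 0.67. The ornithine decarboxylase gene LOC548088, of polyamine synthesis, was at 1.15 ± 0.91. The kinase gene MAPK2 was at 1.39 ± 0.83 and the transcription factor gene BZIP109 at 1.3 ± 0.79. MMP2 was at 2.13 ± 0.72, PC7 at 1.61 ± 1.3, WIN at 1.32 ± 0.63, PR-10 at 1.2 ± 0.17 and H4 at 1.18 ± 0.046. The chlorophyll-binding protein gene CAB3 was at -1.14 ± 0.99 (adjusted p = 0.02). LOC547648, NOD33 and GF14A were at -1.94 ± 0.9, -1.91 ± 0.63 and -1.8 ± 0.16. LOC548016, PGLCAT8 and LOC547630 were at -1.36 ± 0.77, -1.35 ± 0.47 and -1.25 ± 0.79. AMS1, MIPS and PK3 were at -1.16 ± 0.58, -1.14 ± 0.22 and -1.13 ± 0.18.

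In total, 3051 of 18272 probes passed (16.7%), 1280 positive and 1771 negative, with 264 named probes for 169 genes. A gene list with about this share of called probes does not stand out by its counts. The loops did not carry these values equally. CHS1 was at 2.03 and 2.03 in loops 1 and 3 and at 0.11 in loop 2, and CAB3 at -1.56, -1.86 and -0.02. H4 stayed between 1.15 and 1.24 and GF14A between -1.98 and -1.67. On its own 3 loop values no probe passed (4024 at an unadjusted p under 0.05), and without loop 1 or loop 3 only 3 or 109 did.

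**Figure D2:**
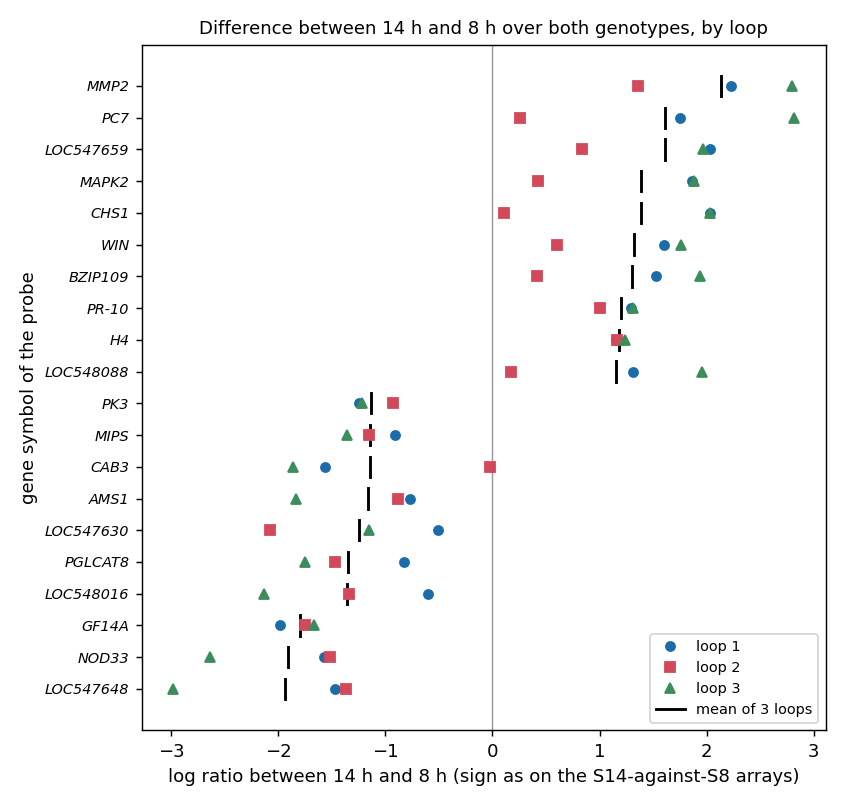
Log ratio between 14 h and 8 h averaged over both genotypes (x axis, as deposited) for the 20 genes named on the 2 sides (y axis), with 1 symbol per loop and a bar for the mean of the 3 loops. H4, PR-10, GF14A, MIPS and PK3 have close symbols, whereas loop 2 lies near 0 for CHS1 (0.11), LOC548088 (0.17) and CAB3 (-0.02).

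By group, 22 of 81 flavonoid and isoflavonoid probes were called positive and 5 negative over both genotypes (39 and 6 adjusted over the list alone). The positive ones belonged to 8 genes, among them CHS1 with 6 of 10 probes, chalcone reductase CHR1 with 2 of 5, isoflavone synthase IFS2 with 2 of 7 and F3H with 4 of 9. The negative ones were all 5 IFR2 probes, between -0.71 and -0.56. The list's median was 0.51 and camera's adjusted p 3e-05, but the adjusted p was 0.4 with an estimated correlation. The median over the 20 genes was 0.65 and 0.58 in loops 1 and 3 and -0.07 in loop 2, and 1 of 11 genes at 0.5 or more in loops 1 and 3 reached that in loop 2. In fry, which tests whether a list moved to one side at all, without reference to other probes, the list did not pass (adjusted p = 0.1). In Williams 82 alone 3 probes were positive and 4 negative (5 and 5 adjusted over the list alone), and in PI194639 alone none passed (1 and 2 adjusted over the list alone).

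Of 6 cell division probes, 5 were positive, 4 for H4 and 1 for the replication factor PCNA (LOC548079, 0.29 ± 0.072). All 6 were positive adjusted over the list alone. Camera's adjusted p was 1.5e-05, with an adjusted p of 0.39 with an estimated correlation. Of 7 root nodule probes, 5 were negative, 3 for NOD33 and 2 for ENOD40B at -0.48 ± 0.02. Camera's adjusted p was 2e-04, and the adjusted p was 0.11 with an estimated correlation. Cell division and nodule genes passed camera in each genotype too, at adjusted p-values of 2.8e-05 and 2e-04 in Williams 82 and 4e-07 and 0.00015 in PI194639. The lists hold only 2 and 4 genes, however, too few for the test with a gene's probes averaged. In each genotype the 4 called cell division probes were all of H4, so this list mainly repeats 1 gene. With an estimated correlation these were 0.38 and 0.11 in Williams 82 and 0.25 and 0.09 in PI194639. Flavonoid, cell wall and calmodulin genes passed camera in each genotype as well. Their adjusted p-values were 2.8e-05, 0.017 and 0.021 in Williams 82 and 0.00033, 0.0086 and 0.02 in PI194639. None passed with an estimated correlation. The nodule list was fixed as a marker of another tissue, and its genes were measured here in stem.

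Cell wall genes were called on the negative side only, with 5 of 12 probes. These included CEL12 at -0.79 ± 0.099, the xyloglucan endotransglucosylase XTH1 at -0.64 ± 0.36 and the expansin EXP1 at -0.48 ± 0.089 (camera adjusted p = 0.0094, and adjusted p = 0.4 with an estimated correlation). Of 14 aquaporin and water stress probes, 6 were negative, among them the aquaporin genes PIP2-6 at -0.82 ± 0.51 and SPCP1 at -0.51 ± 0.11 and the dehydrin MAT1 at -0.33 ± 0.046 (camera adjusted p = 0.038, and adjusted p = 0.4 with an estimated correlation). Of 17 calmodulin and calcium probes, a list added from the symbols, 6 were positive. They included the calcium pump gene SCA1 at 0.97 ± 0.85 and the calmodulin genes SCAM-1 at 0.38 ± 0.13 and SCAM-2 at 0.35 ± 0.16 (camera adjusted p = 0.014, and adjusted p = 0.4 with an estimated correlation). The 5 called of 10 photosynthesis probes were all CAB3 (camera adjusted p = 0.053).

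Since 16.7% of all probes were called for the averaged times, the counts in this paragraph do not by themselves show a response of a group. Transcription factor genes had 4 positive and 13 negative of 82 probes, with MYB50 at -0.56 ± 0.16, MYB176 at -0.54 ± 0.23 and MYB175 at -0.51 ± 0.26 (camera adjusted p = 0.18). Over both genotypes fry passed for root nodule (adjusted p = 2e-04), cell division (0.0021), transcription factor (0.0045), auxin (0.0045), 14-3-3 (0.0045), nitrogen (0.0065), cell wall (0.0085), fatty acid (0.0089), aquaporin (0.016), ribosomal (0.018), calmodulin (0.03), glutathione S-transferase (0.039), protease inhibitor (0.043) and seed storage genes (0.043). Fry makes no reference to other probes, and the variance between loops was 1.51 times the assumed one, so these p-values are too small. Of these lists, only root nodule, cell division, cell wall, aquaporin and calmodulin genes passed camera. The rest had camera adjusted p-values from 0.06 to 0.38, and no list passed camera with an estimated correlation. Both pathogenesis-related genes were positive with all 3 probes, the polygalacturonase inhibitor PGIP being at 0.5 ± 0.3. Peroxidases and other scavenging enzymes split into 3 positive and 1 negative of 26 probes, with PRX4 at 0.79 ± 0.28 and LOC547499 at 0.89 ± 0.61 against CAT5 at -0.92 ± 0.43. Glutathione S-transferases had 3 positive and 1 negative of 28, with GSTF5 at 0.41 ± 0.15 and GSTa at 0.34 ± 0.015 against GST24 at -0.9 ± 0.6. Of 53 jasmonate and ethylene probes 3 were negative, namely VLXB at -0.7 ± 0.28, EREBP1 at -0.64 ± 0.087 and LOX1.1 at -0.44 ± 0.19. None of the 10 phenylpropanoid and lignin probes passed.

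**Figure D3:**
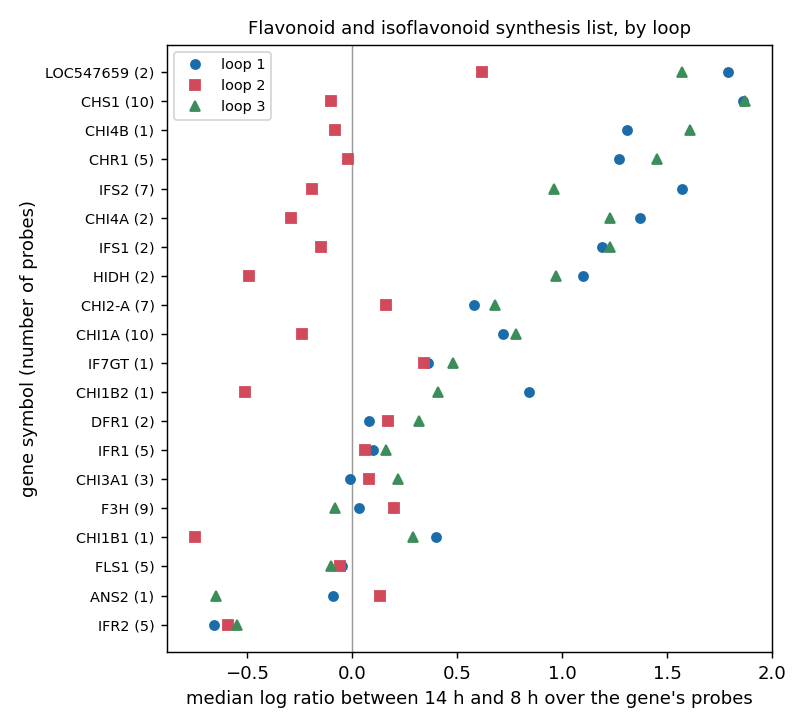
Median log ratio between 14 h and 8 h over a gene's probes, averaged over both genotypes (x axis), for the 20 genes of the flavonoid and isoflavonoid list (y axis, number of probes in brackets), with 1 symbol per loop. Loops 1 and 3 coincide for CHS1 (1.86 and 1.87), where loop 2 is at -0.1, whereas IFR2 lies between -0.66 and -0.55 in all 3 loops.

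Between the genotypes, CGS2 and LOC778108 were called at both times, on opposite sides. The methionine synthesis gene CGS2 (cystathionine gamma-synthase) was at 0.97 ± 0.23 at 8 h (limma adjusted p = 0.014) and 0.98 ± 0.095 at 14 h (adjusted p = 0.017). It rests on 1 of 5 CGS2 probes, and the mean of the 5 was -0.05 at 8 h. The asparaginase gene ASP1 was at 1.13 ± 0.23 at 8 h (adjusted p = 0.03), on 1 of 5 probes. On the same side at 8 h were LOC547735 at 0.79 ± 0.28 and GF14A at 0.76 ± 0.23. On the other side, LOC778108 was at -1.03 ± 0.27 at 8 h and -1 ± 0.31 at 14 h, LOC547759 at -1.04 ± 0.23 at 8 h, the heme oxygenase gene HO3 at -0.67 ± 0.22 at 8 h and the Kunitz trypsin inhibitor KTI3 at -0.78 ± 0.16 at 14 h. The probe Gm05237cDNA18kA, unnamed here, had the smallest adjusted p at both times, 0.002 at 8 h and 0.00032 at 14 h, with 1.34 ± 0.046 and 1.62 ± 0.14. On the other side Gm14925cDNA18kA was at -1.96 ± 0.38 and -1.92 ± 0.91.

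At 8 h 60 probes passed, 19 positive and 41 negative, and at 14 h 38 passed, 12 positive and 26 negative. The lists shared 7 positive probes, where independent lists would share 0.0125, and 20 negative ones, against 0.0583. All 60 and all 38 had the same sign at the other time. The estimates at the 2 times share arrays, so part of this agreement is built in. Genotype values at the 2 times correlated at r = 0.69, at 0.4 on direct arrays alone and at 0.21 in simulated loops with no effect (covariance 0.0378 against 0.00714). Between direct arrays of different loops r ranged from 0.11 to 0.22 only. With the genotype arrays turned, 26 probes passed at 8 h and 69 at 14 h, and 5 of the 7 genes named at 8 h lost their call (all but CGS2 and LOC778108), as did 1 of the 3 named at 14 h (KTI3, adjusted p = 0.14). On their own 3 loop values 114 probes passed at 8 h and none at 14 h (1930 at an unadjusted p under 0.05). Leaving out any 1 of the 3 loops ended all calls at both times (989 to 1721 at an unadjusted p under 0.05 at 8 h, and 1028 to 2790 at 14 h).

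Averaged over both times, 398 probes (2.18% of those tested) differed between the genotypes, 193 positive and 205 negative, with 36 named probes for 31 genes. On the negative side were anthocyanidin synthase ANS2 at -1.31 ± 0.69 (limma adjusted p = 0.021), sucrose synthase SS at -1.11 ± 0.47, AG1 at -1.05 ± 0.29 and F3H at -0.9 ± 0.31. The ethylene-response factor gene EREBP1 was at -0.81 ± 0.44, phosphoglucomutase PGM at -0.72 ± 0.3 and the general transcription factor gene TFIIB1 at -0.69 ± 0.41. LOC778108 was at -1.02 ± 0.27, LOC547759 at -0.96 ± 0.36 and LOC100101848 at -0.87 ± 0.37. On the positive side were ASP1 at 1.01 ± 0.31 (adjusted p = 0.0034), CGS2 at 0.98 ± 0.16 (adjusted p = 0.00065), STP1 at 0.62 ± 0.17, STP at 0.59 ± 0.25, MIPS at 0.56 ± 0.25 and the MADS-box gene SEP1 at 0.47 ± 0.18. LOC547735, LOC547605, LOC547474 and LOC100101840 lay between 0.51 and 0.67. No probe passed on the comparison's own 3 loop values (2304 at an unadjusted p under 0.05) or without loop 1 (1977), 95 passed without loop 3 and 469 without loop 2.

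Of the 81 flavonoid probes, 4 differed between the genotypes, all negative, 3 for F3H and 1 for ANS2 (7 adjusted over the list alone). None of the 10 CHS1 probes passed, with values from -0.25 to 0.19, and both dihydroflavonol reductase DFR1 probes were near 0, at 0.01 ± 0.2 and 0.05 ± 0.33. This was the single list past camera's threshold (adjusted p = 1.2e-06), and its adjusted p was 0.68 with an estimated correlation. It was also the single one at 8 h (adjusted p = 1.3e-07, and 0.78 with an estimated correlation) and at 14 h (adjusted p = 0.00075, and 0.75 with an estimated correlation), where none of its probes passed. Of 28 nitrogen and amino acid probes, a list added from the symbols, 3 were positive, for CGS2, ASP1 and AS2 (0.45 ± 0.16). Camera's adjusted p was 0.23, and 0.68 with an estimated correlation. For the averaged genotypes this was the single list past the threshold in fry, which makes no reference to other probes (adjusted p = 0.036).

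**Figure D4:**
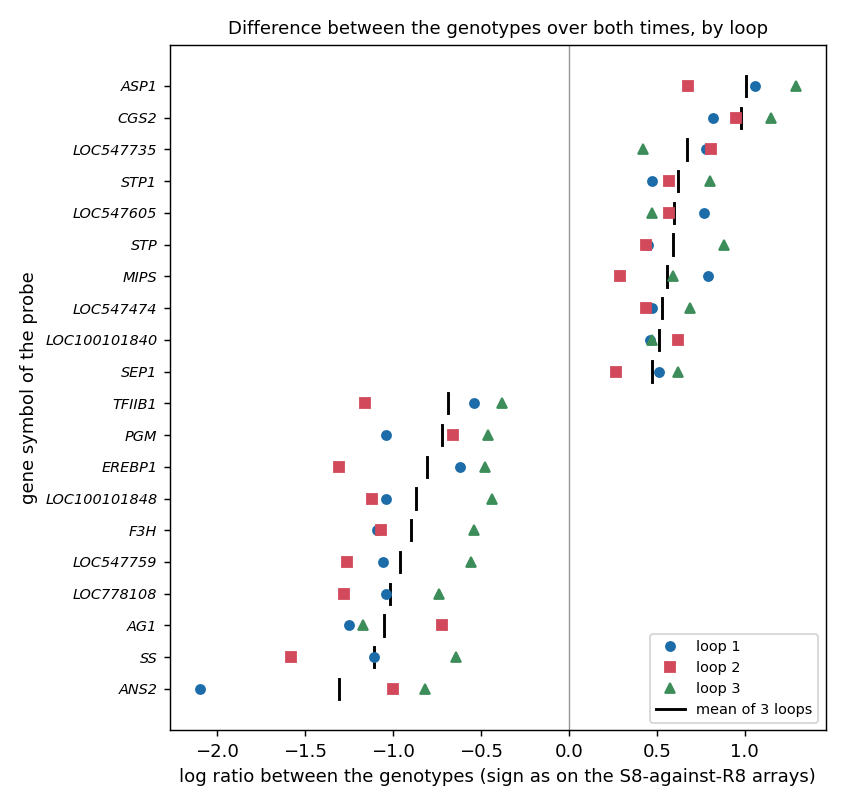
Log ratio between Williams 82 and PI194639 averaged over both times (x axis, as deposited) for the 20 genes named on the 2 sides (y axis), with 1 symbol per loop and a bar for the mean. The genes were chosen for the same sign in all 3 loops, so that sign is no result. ANS2 ranges from -2.1 to -0.82 and CGS2 from 0.82 to 1.15.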

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

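The checks in this part were chosen before the data were examined, except that with turned genotype arrays. Among 218 named probes, 5 had all 3 loops on one side for time in Williams 82 and on the opposite side in PI194639. These were LOC547581 (a difference of -0.54, from -0.19 ± 0.12 in Williams 82 and 0.35 ± 0.28 in PI194639), 1 probe of ASP1 (0.21), the seed storage gene GY1 (0.27), the ribosomal protein gene RPL37 (0.27) and the protease inhibitor gene D-II (0.21). A further 6 were on opposite sides for the genotypes at 8 h and at 14 h. These were LOC547837 (-0.88), ACCB-1, the biotin carrier of acetyl-CoA carboxylase (0.68), MYB182 (0.65), LOC547648 (0.62), UGT1 (0.54) and CG-1 (-0.22). The limma interaction test called none of them, each at an adjusted p of 1. Over all 18272 probes the numbers were 133 for time (0.73%) and 176 for genotype (0.96%). With the signs of the genotype arrays turned, which the labels leave open, 3 of the 5 (D-II, GY1 and ASP1) and 1 of the 6 (UGT1) stayed on opposite sides, and the numbers over all probes were 450 (2.5%) and 534 (2.9%). The 218 probes include those named for the smallest interaction p, which favours opposite sides. Their 5 and 6 are thus not to be set against the shares over all probes. If the titles are right, the turned values hold no difference between the time changes, so the turned numbers are no check on these genes. How many would be met with no difference was not tested.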

How the results depend on the processing

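The tests with turned genotype arrays, without probes holding an exact 0, on a comparison's own 3 loop values and on gene-averaged lists were chosen after seeing the data, as were the correlations without a loop; the others were fixed beforehand. Counts are given in the order time in Williams 82, time in PI194639, genotypes at 8 h, genotypes at 14 h, averaged genotypes and averaged times; the main counts were 646, 133, 60, 38, 398 and 3051. The interaction count was 0 under every setting in which it was fitted, the direct arrays alone not being among them. Median centring, at least 2 complete loops, robust moderation and averaging of a gene's probes kept every count within 1.5 times, although averaging ended the calls of 57 of 145 results for named genes. The first 4 counts were 1869, 867, 191 and 226 with arrays as independent units and no replicate block, and 2026, 931, 200 and 235 with a dye term added; the averaged comparisons moved less. These fits treat arrays sharing an RNA as independent. On the direct arrays alone all 4 were 0 (4520, 2447, 2185 and 1706 probes at an unadjusted p under 0.05), with 3 values per probe. Scaling to equal spread gave 411, 59, 128, 88 and 648 for the first 5; the cause was not tested. A 1.5-fold minimum left 242 and 1165 in the averaged comparisons. An adjusted p of 0.1 gave 1685, 504, 122, 135, 801 and 4694. Turned genotype arrays kept the first count at 582 (380 shared) and gave 644, 26 and 69 for time in PI194639 and the genotypes at 8 h and 14 h. If the titles are right, the turned time values of both genotypes estimate their mean and the turned interaction values hold no interaction. Without probes holding an exact 0 the count at 14 h was 59. The own spread gave 1651, 0, 114, 0, 0 and 0. Without single loops the counts ranged from 0 to 1262, 0 to 1528, 0 to 0, 0 to 0, 0 to 469 and 3 to 3792, with fewer loops in the fit. Lists past camera's threshold numbered 6 for each of the 3 time comparisons and 1 for each of the others. All became 0 with an estimated correlation. None of the lists with at least 5 genes passed with a gene's probes averaged and an estimated correlation (0 in each comparison), and shorter lists were not tested so. Without single loops they numbered 4 to 9 for time in Williams 82, 4 to 9 for time in PI194639, 1 to 4 at 8 h, 0 to 3 at 14 h, 1 to 2 for the interaction, 1 to 3 for averaged genotypes and 4 to 9 for averaged times. The correlation of the time values was 0.63 on direct arrays, and 0.76 to 0.85 without single loops. That of the genotype values was 0.4, and 0.64 to 0.66. Of 145 results for named genes, 86 kept their side of the threshold and their sign with a gene's probes averaged, 122 with turned genotype arrays, 41 with the own spread, 109 without loop 2, 21 without loop 3 and 6 without loop 1. All but the number with turned arrays count as kept 5 interaction results that were never called. Without loop 1 only 1 called result kept its call, for the averaged times. On the direct arrays alone, 0 of 52 did. The genes that changed sign were CGS2 at 8 h (-0.05) and MAPKK2 for averaged times (0.06), both with a gene's probes averaged because other probes differed, and, with turned genotype arrays, the interaction values of GF14A (0.09), UGT1 (0.33), LOC547581 (0.01) and GST24 (0.16), none past the threshold. Signal over background was not analysed here, and 3 loops limit the precision.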

Other observations

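The tests in this part were chosen after the results were seen, except the counts without loop 2 and the interaction test, which were fixed beforehand. Beyond the genes named by rule, the probes of the symbol F3H fell into distinct sets. Over both genotypes, 4 of 9 lay between 0.75 and 0.87 for time (all called), and the other 5 lay between -0.13 and -0.02. On the genotype side the first set lay between -0.61 and -0.42 (none called), and 4 of the other 5 lay between -0.91 and -0.70 (3 called). The sulfur gene OAS-TL3, of cysteine synthesis, also had 1 probe called on each side for time in Williams 82, with 3 probes from -0.59 to 2.02. For time over both genotypes 16.7% of all probes were called, and the list counts that follow are to be read beside that share. Receptor kinase and resistance genes had 4 positive and 1 negative of 11 probes for time over both genotypes, ribosomal protein genes 3 positive of 10, protease inhibitors 2 negative of 15, auxin genes 2 negative of 7 and fatty acid genes 1 positive and 2 negative of 21. Nitrogen genes had 2 positive and 6 negative of 28, seed storage genes 1 and 1 of 28, and 14-3-3 genes 1 negative of 15. Of 4 probes each, vascular and housekeeping genes had 1 negative and heat shock genes 1 positive, and none of 12 protease probes passed. The clock gene LHY had a time value of 0.03 over both genotypes. The largest time values belonged to probes unnamed here, Gm01500cDNA18kA at 3.08 ± 0.72 and Gm11693cDNA18kA at 3.06 ± 0.52 in Williams 82, with Gm14359cDNA18kA at -2.65 ± 0.34 on the other side.

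Loop 2 stood apart from loops 1 and 3 over all probes. Its averaged time values correlated with those of loops 1 and 3 at 0.31 and 0.4, against 0.74 between loops 1 and 3. In PI194639 these were 0 and 0.13 against 0.65, and in Williams 82 0.51 and 0.55 against 0.71. Many flavonoid genes showed it, and so did single genes elsewhere such as CAB3 and LOC548088. Over both genotypes the flavonoid median was 0.65 and 0.58 in loops 1 and 3 and -0.07 in loop 2. On the direct time arrays the medians of loops 1, 2 and 3 were 0.63, 0.27 and 0.36 in Williams 82 and 0.49, -0.5 and 0.68 in PI194639, with CHS1 at 2.14, 1.08 and 2.1 in the former and 1.92, -0.85 and 1.96 in the latter. The averaged value near 0 in loop 2 thus joins opposite values of the genotypes. Equal compression of all ratios in loop 2 would leave a median of 0.21 over both genotypes. The observed -0.07 lay below it by more than the median absolute deviation of 0.21. This does not decide on compression, since the list was singled out for these low values. The deviation is also a spread over genes rather than an error of the median. An exchange of 8 h and 14 h RNA in both genotypes would turn the correlation with the other loops, yet the lower r was 0.31. An exchange in PI194639 alone is argued against, since its time array of loop 2 correlated with the 3 S14-against-S8 arrays at -0.35, -0.21 and -0.17, the sign found in loops 1 and 3, where an exchange would give the opposite sign; a different state of the plants or of the infection stays open, untested.

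Fewer probes passed for time in PI194639 (133) than in Williams 82 (646). Loop 2 alone could produce this, since the PI194639 count was 1528 against 1262 without it. Turning the genotype arrays gave 644 against 582. If the titles are right, however, turning makes both time values estimate the mean of the 2 genotypes. Similar counts would then arise in either case, so this decides nothing about arrays running opposite to their titles. An R8-against-R14 array of loop 2 without any time signal is argued against by those correlations alone, -0.17 or beyond, of which -0.35 is within loop 2. With the R8-against-R14 arrays of loops 1 and 3 it correlated at only 0.08 and 0.14, against 0.58 between those. By these values a weak time signal and a noisier array cannot be told apart. The R14-against-S14 array of loop 2 correlated with the S14-against-S8 arrays of loops 1 and 3 at -0.31 and -0.37. With the R8-against-R14 arrays of those loops it correlated at 0.2 and 0.37. Under the title order, R14 of loop 2 thus lay toward the 8 h side of S14. Noise on the R8-against-R14 array would not produce this. With turned arrays R14 lay beyond S14. This is 1 array, so the question stays open. The time difference rebuilt from the other 3 arrays of loop 2 correlated with loops 1 and 3 at 0.15 at most under the title order and at 0.43 and 0.42 with turned arrays. A smaller change in PI194639 stays open: its slope was lower in 5 of 6 loop pairs under the title order and in 5 of the same 6 with turned arrays (10 of 12), but the ratio of SDs was 1 or more in 3 of 6 under each, and the interaction test called no probe.

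The 4 deposited log ratios of a loop did not sum to 0. The SD of the sum over probes was 0.675, 0.628 and 0.708 in the 3 loops, against 0.883, 0.757 and 0.874 for independent arrays. With the genotype arrays turned it was 0.642, 0.631 and 0.548. The mean of the 4 ratios passed limma's threshold for 3 probes (2580 at an unadjusted p under 0.05). It stands for a dye effect under the title order only. If the genotype arrays run opposite to their titles, it would reflect the interaction instead.

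Other groupings of the same RNAs were tried for each count. For the 4 pairwise comparisons the 10 splits are too few for a share under 0.05; the real split was the 1 with the most probes each time (646, 133, 60 and 38), and the highest other count was 0. For the averaged genotypes, an additive fit called 554 probes, which 1 of 100 drawn splits reached, the real one itself, with 106 as the next highest. For the averaged times it called 3671, which 2 of 100 reached. The other one called 3944, and it kept the real time labels in loops 1 and 3 but set Williams 82 against PI194639 in loop 2, which points to loop 2 as a structure of these samples. Exchanging labels within the 6 pairs gave 32 splits, of which 1, the real one, reached the count, with 725 and 0 as the next highest for times and genotypes. Within the pairs the real labels thus stood out for both averaged counts. These splits exchange the 2 pairs of a loop separately, however, while the replicates are the 3 loops. Exchanging labels by whole loops would leave too few splits to decide. On their own 3 loop values both averaged comparisons called 0 probes, so chance is not excluded for either count. For the interaction the real count was 0, which all 100 splits reach by construction, so they decide nothing. The highest gave 380, and the make-up of that split was not examined.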
